A study of Homo sapiens with 3 samples.

How the data were processed

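The series holds 3 two-colour Agilent arrays of SK-Mel-103 cells at day 3, each on a slide of its own. Channel 1 (Cy5) was RNA of shp62 cells and channel 2 (Cy3) was RNA of shControl cells, per the labels. The labels' protocol names a one-colour labelling kit, whereas the files hold 2 channels per array. No dye swap is given, so dye and hairpin are confounded, and no slide or scan holds more than 1 array, so neither could be a block. The deposited scanner files hold spot intensity values, the median pixel brightness of each spot and of its local background in both channels, made with Agilent Feature Extraction 10.7.1.1, per the file headers. They also hold a log10 ratio of red over green processed signals, after background subtraction and dye normalization by Feature Extraction, per the file headers. The deposited value table of the series holds log2 ratios. The submitters' processing notes name limma without a version, and the individual steps are not given in the sources used here. That table's 3 columns ran in the direction of red over green and had medians of 0.0133, 0.0069 and 0.0039. They correlated across spots at r = 0.991, 0.989 and 0.993 with the log2 ratios computed here; their background offset stays unknown.

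Each array had 45015 spots, of which 1639 were control spots. Signals were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log2 ratios were normalized within each array by loess with control and outlier spots at weight 0. The design fixed beforehand named mean signals. The files used here hold median signals, which took their place. Spots that Feature Extraction marked as non-uniform or as population outliers in either channel, 0.65%, 1.65% and 0.52% per array, were left out. Spots of one probe were averaged. Probes were kept when well above background on all 3 arrays in at least 1 channel and measured on at least 2 arrays, which left 28994 of 41000 probes. Accessions without versions were matched to the RefSeq genes of GRCh38.p14, which named 23680 of all 41000 probes, kept or not, with 16422 symbols. The array design was annotated on an older build, so no coordinates are given. One probe per gene was tested, the one with the highest mean brightness, which gave 22632 genes and transcripts, 396 of them measured on 2 arrays. Of 4432 named genes with more than 1 tested probe, 61 had probes called in both directions.

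An intercept model was fitted with lmFit and eBayes, and p-values are two-sided with Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The median standard error of a log2 ratio was 0.0827. The ratio within an array already pairs its RNAs, so the test measures the spread between the 3 arrays. A total of 39 gene lists were written from textbook knowledge before the data were examined, and 1214 of their 1215 entries matched a symbol of the reference table. They were tested with camera (preset correlation 0.01), which uses genes measured on all arrays, with adjustment over the 39 lists. An estimated correlation and fry were alternatives. With 3 arrays, camera with an estimated correlation has few residual degrees of freedom, so a list that fails it is not thereby shown unchanged. The genes named in the text followed a rule also fixed before the data were examined. It took SQSTM1, FERMT2 and IGF2BP1, the 12 largest rises and 12 largest falls among genes past the threshold with 1 sign on all 3 arrays and a proper symbol, and in each list up to 4 members with the smallest p. Genes outside it are named as such, and some genes that it took are not reported here.

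The procedure was tested on simulated arrays for the comparison of shp62 with shControl, with 200 of 22632 genes changed. With each gene's spread drawn from its moderated SD, 100% of genes with a log2 ratio of -1 or 1 were recovered, 70% of those at -0.5 and 56% of those at 0.5, with 3 unchanged genes among 166 calls. With the unmoderated SD of each gene, the recovery was 44% at -1, 38% at 1, 0% at -0.5 and 2% at 0.5, with 0 unchanged genes among 42 calls. Estimated ratios were slightly small, with medians of -0.92 and 0.88 for true values of -1 and 1 in the first case. Far fewer genes were changed in the simulation than the 32.7% called in the data, and as many were raised as lowered. The recovered shares therefore need not hold for the real arrays. Loess normalization was not tested with many changed genes. Alternatives covered background correction, Feature Extraction's own log ratio, the deposited values, median centring, scale normalization, a separate-channel fit, filters, every probe, outlier spots, the variance model, array weights, a fold minimum of 2 and leaving out each array. Data of the other cell line and time point named in the design text were not analysed here.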

Results

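Gene expression was compared between SK-Mel-103 human melanoma cells that received a short hairpin RNA against SQSTM1 (shp62) and the same cells that received a non-targeting hairpin (shControl), 3 days after lentiviral delivery. SQSTM1 encodes p62, a receptor that carries cargo to autophagosomes and a scaffold in stress signalling. The series comprised 3 two-colour Agilent arrays, and the labels describe 3 biological replicates per condition. Each array held shp62 RNA labelled with Cy5 and shControl RNA labelled with Cy3, so every value below is a log2 ratio of shp62 over shControl. The dyes were not swapped on any array, so a dye effect on a gene cannot be separated from the effect of the hairpin. Between 74.0% and 79.0% of the spots were well above background in the shp62 channel, and between 72.7% and 77.4% in the shControl channel. No spot was saturated. The number of arrays, 3, limits the precision of each value. Across genes, which are not independent replicates, the log2 ratios of pairs of arrays correlated at r = 0.782, 0.742 and 0.813.

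SQSTM1 mRNA fell in the cells with its hairpin. Its log2 ratio was -0.96 (SE 0.08, n = 3), or 0.514 of the shControl level, with an adjusted p of 0.00042 in limma. The 3 arrays gave -0.94, -1.08 and -0.86. The array measured SQSTM1 with a single probe. When arrays were centred on their median without loess, the log2 ratio was -0.37 with an adjusted p of 0.013.

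Of 22632 genes and transcripts tested, 3491 were higher and 3914 were lower with shp62 at an adjusted p of 0.05, which is 32.7% of those tested. Among the 13035 with a current gene symbol, 2176 were higher and 2544 were lower. Most changes were small. The median size of a called change was 1.36-fold, and changes of at least 2-fold numbered 116 among the higher and 348 among the lower genes. The sign was the same on all 3 arrays for 3397 of the higher and 3894 of the lower genes. The 396 tested genes measured on only 2 arrays could not enter these counts. The remaining called genes therefore need not differ in sign between arrays. SQSTM1 was number 399 among the 3914 fallen genes by size, but 1651 of 2417 with median centring and 665 of 3495 with Feature Extraction's log ratio. Without replicate 2, 1471 genes were higher and 2229 lower. With median centring in place of loess, the median of all genes moved from 0.02 to 0.25 and the split became 10424 higher and 2417 lower, so that 18.8% of calls were lower against 52.9%.

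The largest falls were in HSPA13, a microsomal HSP70-family protein, at 9.32-fold (log2 ratio -3.22, SE 0.09), and in RPIA, an enzyme of the pentose phosphate pathway, at 8.10-fold (log2 ratio -3.02, SE 0.13). NAP1L1, a histone chaperone, had a log2 ratio of -2.58 (SE 0.10). It was followed by NCEH1 at -2.47, CEP20 at -2.45, UAP1 at -2.17, SOAT1 at -2.11 and the acetyltransferase KAT2B at -2.06. NMD3, an export adaptor of the large ribosomal subunit, reached -2.01, and LBR, AAGAB and SQLE lay between -1.94 and -1.93. NCEH1 and SOAT1 hydrolyse and form cholesteryl esters, and SQLE is an enzyme of sterol synthesis. A second HSPA13 probe gave -0.51 (adjusted p = 0.038) and a second CEP20 probe -1.05, so the size of these falls differed between probes. Other NMD3 probes gave -1.84 and -1.22. The largest rises were in OLAH, a thioesterase of fatty acid synthesis, at 6.09-fold (log2 ratio 2.61, SE 0.15), and in SLITRK6 at 4.22-fold (log2 ratio 2.08, SE 0.08). The secreted proteins MMP12, TAFA2, INHBA and ORM2 had log2 ratios of 2.01, 1.97, 1.88 and 1.71. MMP12 was above background in shControl on only 2 of 3 arrays, and its ratio ranged from 1.8 to 3.9 over the alternatives, so its size and place are uncertain. IQCN reached 1.90, the chromatin protein HMGA2 1.73, MARCHF3 1.71, the interleukin-1 co-receptor IL1RAP 1.68, the antiproliferative gene BTG2 1.58 and VNN1 1.57. A second HMGA2 probe gave 0.59, and other IL1RAP probes gave 0.62 to 1.39. Adjusted p-values of these 24 genes were at most 0.000685, and each had 1 sign on all 3 arrays. Of 62 called genes taken by the naming rule that had other tested probes, all the others were called the same way for 45, some were not called for 17, and 0 had a probe called the opposite way. For 17 of the 62, another probe gave a fold more than 1.5 times smaller. FERMT2, which encodes kindlin-2, an activator of integrins, fell with a log2 ratio of -1.19 (SE 0.09, adjusted p = 0.00027). IGF2BP1, an mRNA-binding protein, had a log2 ratio of 0.29 (SE 0.10) and did not pass the threshold, with an adjusted p of 0.070. Its 3 arrays gave 0.01, 0.43 and 0.43, and a second probe gave 0.53 with an adjusted p of 0.0056. It passed without replicate 1, at 0.43 with an adjusted p of 0.018, and with median centring, at 0.72, and also with the deposited values (adjusted p = 0.041) and with array weights (adjusted p = 0.037).

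**Figure D1:**
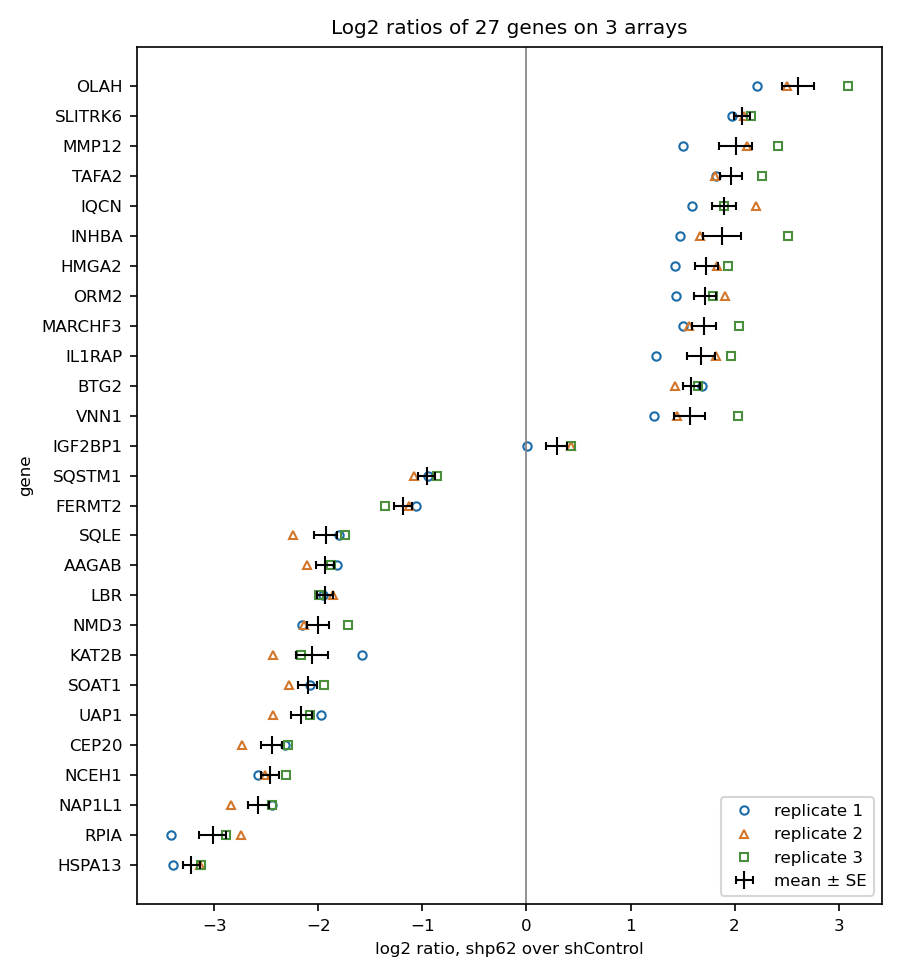
Log2 ratios of shp62 over shControl (x axis) for SQSTM1, FERMT2, IGF2BP1 and the 12 genes with the largest rise and the 12 with the largest fall (y axis). Open symbols are the 3 arrays and bars are the mean ± SE; HSPA13 lies at -3.22, OLAH at 2.61 and SQSTM1 at -0.96.

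Most genes of cell division fell. Of 47 mitotic genes tested, 45 were lower and 0 were higher (45 lower adjusted over the list alone), with a median log2 ratio of -0.98. They included NUF2, a kinetochore protein, at -1.81 (SE 0.10), the spindle checkpoint gene MAD2L1 at -1.43 (SE 0.11), the mitotic kinase AURKA at -1.23 (SE 0.08) and HMMR at -1.18 (SE 0.09). Of 45 genes of the G1/S transition and DNA replication, 34 were lower and 1 was higher (36 and 1 adjusted over the list alone), with a median of -0.54. Examples were the transcription factor E2F2 at -1.71 (SE 0.13), the clamp loader subunit RFC3 at -1.60 (SE 0.15), and RRM1, a subunit of ribonucleotide reductase, at -1.10 (SE 0.11). Other probes of E2F2 and RFC3 gave -0.19, which was not called, and -0.71. Both lists passed limma's camera test with a preset correlation between genes, with adjusted p-values of 4.28e-19 and 3.14e-12 over 39 lists. With a correlation estimated from these 3 arrays, none of the 39 lists passed camera. The adjusted p was 0.710 for both of these lists, from unadjusted values of 0.224 and 0.270. Many lists shared this adjusted value, so it does not tell them apart. The smallest unadjusted p of any list was 0.052, for NF-κB targets. With 3 arrays this form of camera has few degrees of freedom, so not passing it does not decide against a list. With median centring their medians were -0.53 and -0.24, against a median of 0.25 over all genes. In fry's directional test, which does not compare a list with other genes, the adjusted p was 0.081 for the mitotic and 0.11 for the replication list, so neither passed.

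Some genes of cholesterol synthesis were lower. Of 25 tested, 12 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 ratio of -0.28 and an adjusted p of 3.6e-05 with the preset correlation and of 0.710 with an estimated correlation. Beside SQLE, they included the enzymes MSMO1 at -1.63 (SE 0.13) and LSS at -0.95 (SE 0.08), for which 2 of 3 other probes were not called and the range was -0.56 to -0.05. With median centring the list did not pass (adjusted p = 0.17) and its median was 0.11, again against 0.25 over all genes. Random lists of equally bright genes had a median of 0.47 in that fit, and the cholesterol list lay at percentile 0 of them. The list had been picked as lower from the same values, so this adds no independent support. In fry's directional test the cholesterol list did not pass either (adjusted p = 0.081). Among 25 genes of fatty acid and lipid synthesis, 9 fell and 4 rose (13 and 4 adjusted over the list alone). This list did not pass in the main camera test, with an adjusted p of 0.058. It passed as lower with no filter on dim probes (0.028), with array weights (0.049), without replicate 1 (0.011) and without replicate 2 (0.046). The desaturases FADS2 and FADS1 had log2 ratios of -0.86 and -0.78, which did not pass with median centring (-0.21 and -0.19), and a second FADS2 probe at -0.37 was not called.

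More ribosomal protein genes rose than fell, and under loess more genes that assemble ribosomes fell than rose. Of 49 ribosomal protein genes, 32 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 ratio of 0.45, and of 1.33 with median centring. Random lists of equally bright genes had medians of 0.16 and 0.95 in these settings, so part of each value is shared by bright genes. Examples were RPS14 at 0.80 (SE 0.08), RPL38 at 0.76 (SE 0.09) and RPS15 at 0.74 (SE 0.09). A second RPS14 probe at 0.21 was not called. These are among the brightest spots, many of which were excluded as outliers on replicate 2, so the camera test rested on the 18 members measured on all 3 arrays. Its adjusted p was 1.1e-06, and 0.710 with an estimated correlation, and it did not pass in fry's directional test (adjusted p = 0.079). Of 30 genes of ribosome biogenesis, 15 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.22 and an adjusted p of 0.0039 (0.710 with an estimated correlation), but the direction turned with median centring (median 0.30, adjusted p = 0.50). NPM1, a nucleolar phosphoprotein, was at -0.74 (SE 0.08), RRS1 at -0.68 (SE 0.08) and GNL3 at -0.67 (SE 0.09). None of these 3 passed with median centring, at -0.03, -0.11 and -0.11. Of 36 proteasome genes, 14 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -0.16 and an adjusted p of 0.0042 (0.710 with an estimated correlation), and the direction turned with median centring (median 0.47, adjusted p = 0.048). The subunit PSMA2 was at -0.91 (SE 0.08). PSMD11 was at -0.74 (SE 0.08) and did not pass with median centring. Of 25 chaperone genes of the heat-shock response, 10 fell and 0 rose (10 and 1 adjusted over the list alone), with a median of -0.15 and an adjusted p of 0.012 (0.710 with an estimated correlation), and this direction also turned with median centring (median 0.34, adjusted p = 0.87). The mitochondrial chaperonins HSPE1 and HSPD1 were at -1.08 (SE 0.10) and -0.78 (SE 0.09), and HSPD1 was at 0.06 with median centring. In fry's directional test ribosome biogenesis did not pass (adjusted p = 0.079). Set against random lists of equally bright genes, a comparison added after the data were seen, the 3 list medians lay below the central 95% both with loess and with median centring. These 3 lists had been picked as lower from the same values, so this adds no independent support.

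Among targets of NF-κB and p53, matrix genes and lysosomal genes, more were higher than lower, and many were not called. Of 31 targets of NF-κB, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 ratio of 0.28 and an adjusted p of 0.00013 (0.710 with an estimated correlation). They included the cytokine IL1A at 0.93 (SE 0.13), the adhesion molecule ICAM1 at 0.80 (SE 0.08), the NF-κB inhibitor NFKBIA at 0.75 (SE 0.08) and LIF at 0.62 (SE 0.07), of which a second probe at 0.13 was not called. Of 43 genes of the extracellular matrix and its remodelling, 17 rose and 4 fell (17 and 4 adjusted over the list alone), with a median of 0.15 and an adjusted p of 0.0069 (0.710 with an estimated correlation). ADAM12 was at 1.14 (SE 0.07), the laminin chain LAMC1 at 1.06 (SE 0.08) and the matrix metalloproteinase MMP15 at 0.97 (SE 0.07). Second probes of ADAM12 and MMP15 gave 0.36 and 0.42. LUM, which is also on the list of fibroblast markers, was at 1.06. The matrix list did not pass without replicate 1 (adjusted p = 0.065). Of 36 lysosomal genes, 13 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.15 and an adjusted p of 0.0069 (0.710 with an estimated correlation). The proteases CTSS and TPP1 were at 1.34 (SE 0.08) and 0.81 (SE 0.09), and a second CTSS probe at 0.12 was not called. Of 28 targets of p53, 13 rose and 3 fell (16 and 4 adjusted over the list alone), with a median of 0.24 and an adjusted p of 0.017 (0.736 with an estimated correlation), and the list did not pass without replicate 3 (adjusted p = 0.074). Beside BTG2, the death receptor FAS was at 1.11 (SE 0.13) and SPATA18 at 0.77 (SE 0.08), whereas the nuclease AEN was at -0.74 (SE 0.10). In fry's directional test the matrix (adjusted p = 0.081) and p53 (adjusted p = 0.11) lists did not pass.

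Among targets of the antioxidant factor NRF2 and interferon-stimulated genes, more were lower than higher, but 15 of 30 and 25 of 36 were not called. Of 30 NRF2 targets, 12 fell and 3 rose (13 and 3 adjusted over the list alone), with a median log2 ratio of -0.20 and an adjusted p of 0.032 (0.710 with an estimated correlation). CBR3 was at -1.13 (SE 0.13), GCLM, a subunit of the enzyme that limits glutathione synthesis, at -0.84 (SE 0.07) and the thioredoxin reductase TXNRD1 at -0.71 (SE 0.12). This list did not pass with median centring (median 0.30, adjusted p = 0.91), without replicate 2 (adjusted p = 0.12) or with spots required above background in both channels (adjusted p = 0.060), and TXNRD1 was at -0.29 with median centring. Of 36 interferon-stimulated genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.19 and an adjusted p of 0.025 (0.797 with an estimated correlation). IFIT1 was at -1.39 (SE 0.24), with -0.57, -2.08 and -1.51 on the 3 arrays, and IFIT5 was at -0.99 (SE 0.11), whereas TRIM22 was at 0.73 (SE 0.09). The interferon list did not pass without replicate 2 (adjusted p = 0.21) or without replicate 3 (adjusted p = 0.13). In fry's directional test neither list passed (adjusted p = 0.082 and 0.42).

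**Figure D2:**
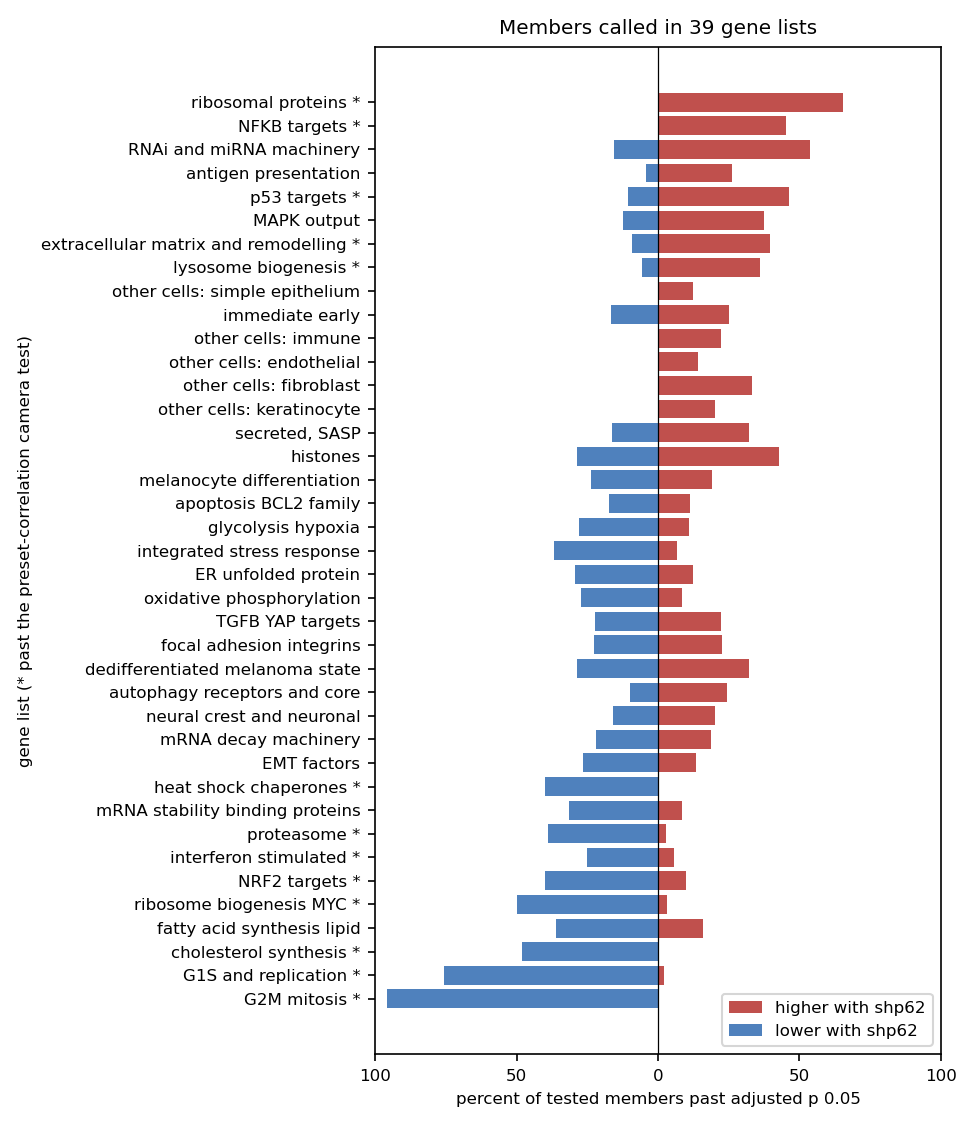
Percent of the tested members of each gene list (x axis) that were higher (right) or lower (left) with shp62 at an adjusted p of 0.05, for 39 lists fixed beforehand (y axis) ordered by median log2 ratio. Asterisks mark the 13 lists past the camera test with the preset correlation; 45 of 47 mitotic genes were lower and 32 of 49 ribosomal protein genes were higher.

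Genes of mRNA turnover, named in the title of the series, changed in both directions. Of 59 genes of the mRNA decay machinery, 11 rose and 13 fell (11 and 16 adjusted over the list alone). The list did not pass camera (adjusted p = 0.50). With median centring it passed as higher, with a mean of 0.40 (adjusted p = 0.048). In that fit its median lay at percentile 16.5 of random lists of equally bright genes, so it was not higher than genes as bright. The exosome subunit EXOSC2 was at -1.27 (SE 0.09), the exonuclease XRN1 at -0.90 (SE 0.09) and TNRC6A, which links microRNAs to deadenylation, at 1.07 (SE 0.11). A second XRN1 probe at -0.07 was not called. Of 35 mRNA-binding proteins that affect stability, 11 fell and 3 rose (12 and 3 adjusted over the list alone; adjusted p = 0.13), with FMR1 at -1.06 (SE 0.08) and CELF1 at -0.73 (SE 0.09). Of 13 genes of RNA interference and microRNA processing, 7 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.11). DICER1 was at 1.01 (SE 0.09), AGO4 at 0.87 (SE 0.07) and TARBP2 at 0.68 (SE 0.08). This list passed with median centring, with an adjusted p of 0.023, and lay at percentile 99.7 of equally bright lists in that fit. Of 41 autophagy genes, 10 rose and 4 fell (12 and 5 adjusted over the list alone; adjusted p = 0.997), with ATG7 at 0.61 (SE 0.08) and ATG4A at -0.78 (SE 0.08). The autophagy list had a median of -0.06 and a mean of 0.01, and it passed with median centring (adjusted p = 0.034). In that fit it lay at percentile 57.3 of equally bright lists, so it was not higher than genes as bright.

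Adhesion and melanoma state genes were also mixed. Of 40 genes of focal adhesions and integrins, 9 rose and 9 fell (11 and 9 adjusted over the list alone; adjusted p = 0.87). The integrin chains ITGA5 and ITGA2 were at 0.99 (SE 0.09) and 0.94 (SE 0.08), and the caveolar protein CAV1 was at -0.99 (SE 0.08). Of 21 melanocyte differentiation genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.96), and of 28 genes of the dedifferentiated melanoma state 9 rose and 8 fell (11 and 9 adjusted over the list alone; adjusted p = 0.73). For these 2 lists the median, the mean and the test differed in sign, since the values lay near 0. Among 31 secreted and prometastatic genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone; adjusted p = 0.26). The collagenase MMP1 was at 1.33 (SE 0.14) and SERPINB2 at 1.30 (SE 0.13), while FGF2 was at -0.82 (SE 0.08). Of 35 apoptosis genes, 4 rose and 6 fell (4 and 5 adjusted over the list alone; adjusted p = 0.72), with BIRC5 at -1.24 (SE 0.13) and BIK at 0.85 (SE 0.08).

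Markers of other cell types were measured as a sign of RNA from other cells. Of 8 simple epithelial markers tested, 1 rose, which was CLDN4 at 1.33 (SE 0.08), while EPCAM was at 0.14 and did not pass. Of 3 fibroblast markers, 1 rose, which was LUM, while THY1 was at 0.03 and passed at 0.41 with median centring. KRT10 (0.77), KRT18 (0.89), TWIST2 (0.51), FCER1G (0.57) and CD79A (0.52) did not pass in the main analysis and passed as higher with median centring, and KRT18 also with the deposited values (0.25). EPCAM turned to -0.19 with median centring without passing. IVL was not above background in shControl on any array, so its ratios are not measured values. Of 9 immune markers, 2 rose, LYZ at 0.36 and CD68 at 0.35. LYZ and TEK were above background in shControl on only 2 of 3 arrays. Of 7 endothelial markers, 1 rose, TEK at 0.36, and of 5 keratinocyte markers, 1 rose, KRT14 at 0.35 (adjusted p = 0.04996). Adjusted over the list alone, the counts were 1 epithelial, 1 fibroblast, 2 immune, 1 endothelial and 0 keratinocyte markers, and 0 markers were called lower in the 5 lists in the main analysis. None of these lists passed camera with the preset correlation, with adjusted p-values of 0.30, 0.25, 0.11, 0.80 and 0.64 in the order given from epithelial to keratinocyte markers. In fry's directional test the fibroblast and endothelial lists passed, both with an adjusted p of 0.049. ERG, an endothelial marker, was at -0.24 (adjusted p = 0.054) and passed as lower in 6 alternative settings, and KDR was at 0.20 and passed as higher in 3. Without replicate 2, LYZ, CD68, TEK and KRT14 did not pass, with adjusted p-values of 0.064, 0.070, 0.065 and 0.11. Without replicate 1, CD68 and KRT14 had adjusted p-values of 0.053 and 0.17, and without replicate 3 TEK had one of 0.080. KRT14 also missed the threshold in 4 other settings, with adjusted p-values from 0.052 to 0.064, and TEK and LYZ missed it with median centring (adjusted p = 0.42 for both).

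**Figure D3:**
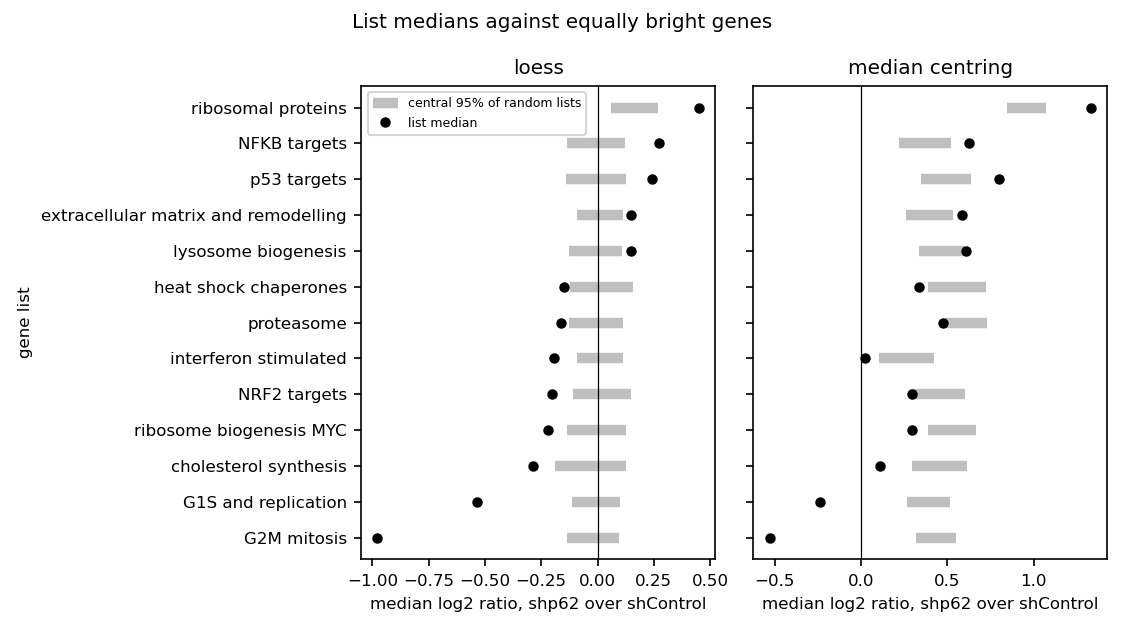
Median log2 ratio of shp62 over shControl (x axis) of the 13 gene lists past the preset camera test (y axis), with loess (left) and with median centring (right). The lists were picked by that test from the same values. Points are list medians and grey bars hold the central 95% of 10000 random lists of equally bright genes; the mitotic list lies at -0.98 and -0.53, below its bar in both panels, and the NRF2 list lies within its bar with median centring.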

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

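The comparisons with lists of equally bright genes were added after the results were seen; the other alternatives were fixed before the data were examined. SQSTM1 stayed lower at an adjusted p below the threshold, from -1.01 to -0.37, under all alternatives except the fold minimum of 2, which its ratio of -0.96 does not reach, and from -1.01 to -0.90 with 1 array left out. Counts of changed genes were within 1.5 times of the main counts, except with median centring (10424 higher, 2417 lower), with a fold minimum of 2 (116 higher, 348 lower) and without replicate 2 (1471 higher, 2229 lower). Leaving out 1 array gave 1471 to 2947 higher and 2229 to 3398 lower genes. The place of SQSTM1 among fallen genes was 1651 with median centring and 665 with Feature Extraction's own log ratio, and 316 to 510 with 1 array left out. Of 39 lists, 12 to 16 passed under the other processing settings and 12 to 14 with 1 array left out, but 0 passed with an estimated correlation, 7 in the directional and 38 in the mixed test of fry. The 7 were 4 of the 13 main lists (lysosome, NF-κB, heat-shock chaperones and proteasome) and oxidative phosphorylation, fibroblast and endothelial markers. Against equally bright genes, 18 lists lay outside the central 95% with loess and 15 with median centring. With median centring the mean of 21 of 39 lists changed sign, among them the NRF2 (0.21), cholesterol (0.04) and interferon (0.02) lists, whose test direction stayed lower. The direction of the camera test, which is relative to other genes, turned for 6 lists that passed in at least 1 of the 2 fits, with means of 0.26 (heat-shock chaperones), 0.41 (proteasome), 0.29 (ribosome biogenesis), 0.40 (mRNA decay), 0.44 (glycolysis and hypoxia) and 0.42 (oxidative phosphorylation). Of 168 named genes other than SQSTM1, 15 changed sign, 13 of them with a call in at least 1 of the 2 fits, MLPH (0.10), PAX3 (0.077), TCF4 (0.11), FOXC1 (0.14), PHLDA2 (0.036), SYNCRIP (0.076), TRIB3 (0.14), EPRS1 (0.078), PDIA4 (0.028), HSPD1 (0.059), PSMB4 (0.087), TUBB3 (0.046) and IVL (-0.35, not a measured value, since shControl was not above background), the other 2 being KDR (-0.16) and EPCAM (-0.19), and 24 others lost their call. Median centring leaves the trend of ratio with brightness in place. The loess and median-centred ratios of a gene differ only by a curve of ratio on brightness in each array. These changes between the 2 fits therefore come from that trend. Without replicate 2, 14 of 168 named genes lost their call, without replicate 1 6 of 165, and without replicate 3 3 of 165; 0 turned. Between 72.7% and 79.0% of the spots of a channel were well above background. With probes required well above background in both channels, 3379 genes were higher and 3849 lower. The ratio within an array pairs its 2 RNAs, so the main analysis is itself a paired one.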

Other observations

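The families by symbol and the comparison of other probes over all called genes were chosen after the results were seen. Several lists fixed beforehand held called genes without passing as lists. Of 48 genes of oxidative phosphorylation, 13 fell and 4 rose (13 and 4 adjusted over the list alone; adjusted p = 0.052), with UQCRFS1 at -1.06, NDUFV2 at -0.999 and COX7C, measured on 2 arrays, at 1.28. The list passed as lower with no filter on dim probes (0.016), without replicate 3 (0.032) and in fry's directional test (0.046), and as higher with median centring (mean 0.42, adjusted p = 0.040). Of 36 genes of glycolysis and hypoxia, 10 fell and 4 rose (11 and 4; adjusted p = 0.42), with PDK1 at -1.003 (a second probe at -0.24 was not called) and the demethylase KDM3A at 1.17, and with median centring the list passed as higher (mean 0.44, adjusted p = 0.042). Genes of the integrated stress response had 11 lower and 2 higher of 30 (adjusted p = 0.25), and those of the unfolded protein response 7 lower and 3 higher of 24 (adjusted p = 0.45), and the second of these passed as lower without replicate 1 (adjusted p = 0.025). Antigen presentation genes had 6 higher and 1 lower of 23 (adjusted p = 0.12), with HLA-B at 0.69, and this list passed with median centring and without replicate 3. Outputs of MAPK signalling had 9 higher and 3 lower of 24 (adjusted p = 0.28), with SPRED1, an inhibitor of RAS signalling, at -1.70 (-0.82 with a second probe), and this list passed as higher with median centring (adjusted p = 0.023). Immediate early genes had 6 higher and 4 lower of 24 (adjusted p = 0.55), with KLF4 at 0.94 and KLF2 at -0.99, of which a second probe at -0.12 was not called. Targets of TGF-β and YAP had 6 higher and 6 lower of 27 (adjusted p = 0.34), with NT5E at 1.24. Factors and markers of the epithelial-mesenchymal transition had 2 higher and 4 lower of 15 (adjusted p = 0.37), with the transcription factor ZEB2 at 0.50, the cadherin CDH2 at 0.47, TCF4 at -0.33 and FOXC1 at -0.45. TCF4 did not pass with Feature Extraction's log ratio (adjusted p = 0.078), without replicate 2 (0.092) or without replicate 3 (0.053). FOXC1 did not pass without replicate 1 (adjusted p = 0.053). With median centring TCF4 and FOXC1 turned to 0.11 and 0.14. Neural crest genes had 5 higher and 4 lower of 25 (adjusted p = 0.57), with TUBB3 at -0.64, which turned to 0.05 with median centring. Histone genes had 6 higher and 4 lower of 14 (adjusted p = 0.47), with H2AX at -1.28; their median was 0.02 and their mean -0.04. Adjusted over the list alone, the higher and lower counts were 2 and 11, 3 and 7, 5 and 1, 9 and 3, 6 and 5, 6 and 8, 2 and 5, 5 and 4, and 6 and 4 in the order given from the integrated stress response to histones.

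Among 83 families of genes with a shared symbol stem and at least 15 members measured on all arrays, 5 passed with the preset correlation and 0 with an estimated one (adjusted p = 0.829). Of 16 matrix metalloproteinase genes, 9 rose and 0 fell (adjusted p = 0.0091). Beside MMP12, MMP1 and MMP15, they included MMP10 at 0.82, MMP19 at 0.77 and MMP2 at 0.69. Of 25 keratin genes, 9 rose and 0 fell (adjusted p = 0.0091), with KRT6B at 0.84 and KRT23 at 0.79. Of 34 genes named for centrosomal proteins, 11 fell and 2 rose (adjusted p = 0.013), with CEP55 at -1.33 beside CEP20. Interleukin and interleukin receptor genes had 14 higher and 6 lower of 44 (adjusted p = 0.0091), with IL32 at 1.14 and IL31RA at 1.13. The stem RPL had 12 higher and 2 lower of 25 (adjusted p = 0.042). With median centring these adjusted p-values were 0.12, 0.17, 0.34, 0.43 and 1.6e-06. The stem RPS had 7 higher and 3 lower of 19 and did not pass (adjusted p = 0.21, and 0.018 with median centring). The members named here were chosen after their values were seen.

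The number of changed genes is the first pattern to follow up. Turning the sign of 1 array in each of the 4 possible patterns is the only regrouping these arrays allow, and it is too few for a share under 0.05: the real signs, 1 of the 4, gave 7405 called genes and the highest of the others gave 0, and for lists the real signs, 1 of the 4, gave 13 and the highest of the others 11. With 1 array turned, a shared shift stays in the other arrays and widens the spread between arrays. Any reproducible shift, a dye bias included, would then give few called genes. Neither comparison therefore argues for or against the called genes or the lists. A dye bias of single probes would leave other probes of a called gene without a common direction. Of 2388 other probes of called genes, 88.5% went the called way (exact 95% interval 87.1% to 89.7%), which argues against it as the whole cause. A dye bias shared by all probes of a transcript, and an effect of the hairpin on genes other than SQSTM1, stay open, since dyes were not swapped and 1 hairpin was used.

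The fall of the mitotic and replication genes is the second pattern. All 29 other probes of their members (100%) were negative, against 50.6% of all other probes of named genes, which argues against a bias of single probes. Both lists' medians lay at percentile 0 of 10000 lists of equally bright genes with loess and with median centring, which argues against a trend of the ratio with brightness. The rise of ribosomal protein genes lay at percentile 100 in both. These genes are among the brightest, and their random lists, matched in 50 brightness bins, had medians of 0.16 with loess and 0.95 with median centring. A trend within the brightest bin would not be matched, so the percentile does not decide on that trend for these genes. Of 45 other probes, 77.8% were positive (62.9% to 88.8%), which leaves a bias of single probes open. No biological explanation was tested.

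The third pattern is the direction of the proteasome, chaperone, ribosome biogenesis and respiratory lists, which turned with the normalization. With median centring the median ratio went from -0.19 in the dimmest of 5 equal groups of genes to 0.55 in the brightest. With median centring, the highest of the 4 list medians lay at percentile 23.5 among equally bright genes. That value decides nothing by itself, since the 4 lists were picked as lower after loess, which removes the same trend. Both fits share background correction, probes and brightness values, and differ only by a curve of ratio on brightness in each array. The turn between them therefore came from the trend. Which of the fits lies nearer to the true ratios was not tested. Of the 13 lists past the preset test, 12 lay outside the central 95% in the same direction under both normalizations, and the exception was the NRF2 targets, at percentile 3.36 with median centring. The 13 lists were picked for their shift in the same values, and the random lists ignore correlation between genes. This count is therefore no independent support for the lists. The same normexp offset was added to both channels, whose median signals differed. They were 400 for shp62 and 128 for shControl on replicate 1, 432 and 146 on replicate 2, and 449 and 234 on replicate 3. The trend went from -0.30 to 0.66, from -0.26 to 0.59 and from -0.04 to 0.38 on these arrays. Whether this processing made part of the trend was not tested. Dyes and RNAs cannot be told apart as its source without a dye swap.

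The spike-in regressions in the file headers had slopes of 0.896, 0.928 and 0.912 of observed on expected log10 ratios, with intercepts of -0.02, 0.23 and 0.30, also in log10 units. The intercepts thus differed between arrays. Normalization centred the ratios on the bulk of each array's genes and not on the spike-ins. Higher and lower, and the split of calls between them, are therefore relative to that bulk.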
